A study of Huso dauricus with 9 samples.

How the data were processed

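The series holds poly(A) RNA-seq of gut tissue from kaluga sturgeon (Huso dauricus) released into a river for stock enhancement. Per the labels, the 9 libraries fall into 3 groups of 3 fish: Ori (day 0), D14FL (day 14) and D30FL (day 30 after release). Fish were recaptured at each time, so a replicate number names a different fish in each group. A further time point that the design text names was not analysed here.

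Per the labels' protocols, RNA was selected with oligo(dT) and the second strand was digested before amplification. The submitters' processing notes name cutadapt 1.9 and the mouse build mm10, with no role given for the build, which no step here uses. The quantification tool and the read depth are not given in the sources used here. The deposited table lists 59331 transcripts of a de novo assembly, whose row names have the form Trinity gives plus an ending of 1, 2 or 3 of unknown meaning (a reading frame or an isoform, for example); each row was treated as a transcript. The table comes with annotation against public protein databases. Per the file headers and the file's own name, its values are FPKM (fragments per kilobase of transcript, scaled by library size). They sum to between 810895 and 929953 per library. TPM over a filtered list would look alike, so the unit rests on the name alone. Values above 0 reach down to 3.63e-118, which whole reads do not give, so reads were not recovered. Depth is therefore unknown, and no counting interval or detection limit is given. An exact 0 is described as listed at 0. Without a genome, transcripts have no coordinates, and transcripts of near-identical gene copies may share reads.

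Transcripts with FPKM of at least 1 in at least 3 libraries were tested, 54200 in all. The test was limma 3.58.1 (lmFit, contrasts and eBayes with trend) on log2(FPKM + 1) in R 4.3.3, over all 9 libraries and without a block. The residual degrees of freedom were 6 and the prior degrees of freedom 5.73. Calls used a Benjamini-Hochberg adjusted p under 0.05, in tests of both directions. A log2 change on this scale understates the change of low transcripts. Tables were handled in R with data.table (version 1.17.8) and in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

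Gene symbols were matched to the Swiss-Prot gene name of each transcript, to its Swiss-Prot entry name also where a gene name was given, and to its KEGG gene name otherwise. The use of the entry name beside a gene name and of KEGG names departs from the plan; it was set after the annotation columns were seen and before any test was run, as were 61 pairs of a symbol and a protein of another name that were left out. The species of a transcript is that of its best match in the non-redundant protein database, a column with an entry for 29076 transcripts. The transcripts named in the text followed a single rule. For each contrast it took the 10 highest and 10 lowest log2 changes among called, named transcripts with a mean FPKM of at least 5 in the higher group and no overlap between the 3 values of each group. Where no named transcript was called, it took the 5 highest and the 5 lowest by p. For each gene list it added up to 4 members with the smallest p.

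The 41 gene lists were written from general knowledge of gut and fish biology, with the transcript of highest mean FPKM standing for each symbol. Of 1188 listed symbols, 935 were found and 905 tested. The lists were brush border enzymes and microvillus proteins, nutrient transporters, lipid uptake and lipoprotein assembly, pancreatic digestive enzymes, mucus and goblet cells, enteroendocrine cells, tight and adherens junctions, cell cycle, apoptosis, fatty acid oxidation and ketogenesis, fatty acid synthesis, sterol synthesis, glycolysis, gluconeogenesis, amino acid breakdown, oxidative phosphorylation, ribosomal proteins, proteasome subunits, autophagy and lysosome, endoplasmic reticulum stress, heat shock proteins, antioxidant defence, glucocorticoid and acute stress genes, circadian clock, xenobiotic metabolism, inflammatory cytokines and NF-kappaB, interferon response, antigen presentation, complement, antimicrobial effectors, microbe sensing, macrophages and granulocytes, T and natural killer cells, B and plasma cells, erythrocytes, endothelium, extracellular matrix and fibroblasts, smooth muscle, skeletal muscle, enteric neurons and glia, and liver. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists. Beside it stand camera with an estimated correlation and fry.

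The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were other pseudocounts (0.1 and 0.01), other filters, median-of-ratios and quantile scaling, an adjusted p under 0.1, a minimum of 2-fold, other limma settings, library weights, the replicate number as a block, fits on only the 2 groups compared, and each library left out in turn. A fit without transcripts whose best match is a mammal, bird or bacterium was added after seeing the data. The unpaired fit was kept, since the numbers name different fish. The covariance of the day 14 and day 30 changes was set against 50 simulations of unchanged groups measured against the same Ori libraries. The simulations drew each transcript independently of the others.

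The transcript test was tested on simulated data for D14FL minus Ori on 46203 features. It recovered 37 of 50 features raised by 3 log2 units and 27 of 50 raised by 2, 38 of 50 lowered by 3 and 23 of 50 lowered by 2, with 4 false calls. The changed features were drawn from those with a mean log2(FPKM + 1) above 3 in Ori. Median values of tested transcripts in the Ori libraries lay between 1.52 and 1.91, so recovery among lower transcripts was not measured. The list test, simulated for D30FL minus Ori on the same features, found the cell cycle list lowered by 1 log2 unit and called 0 other lists. Simulated features varied independently of each other. The simulation therefore does not show how the list test behaves where the genes of a list vary together.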

Results

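The data are transcript levels in the gut of 9 kaluga sturgeon, a large migratory fish of the Amur basin that is reared and released to support its stock. There were 3 fish at day 0 (Ori), 3 at day 14 (D14FL) and 3 at day 30 (D30FL) after release into the river, each measured as 1 library. The series asks how stock enhancement affects the intestine, and the comparisons below set the gut of fish at days 14 and 30 against day 0 and against each other. No label gives a batch, and no fish kept in the hatchery to day 14 or 30 are among the samples, so time since release, date, food and any library batch cannot be told apart. Values are the authors' FPKM, and the read depth behind them is unknown. Of 59331 assembled transcripts, between 35812 (Ori 1) and 49503 (D30FL 2) had an FPKM of at least 1 in a library.

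The Ori libraries stood apart from the later ones on the first principal component, but not in every pairwise correlation. On the first principal component, which held 42.1% of the variance, the Ori libraries lay between -149.8 and -116.8 and the 6 later libraries between -36.5 (D30FL 3) and 183.5 (D30FL 2). Pearson correlations of log2 values across transcripts, which are not independent replicates, ran from 0.830 to 0.887 within Ori and from 0.830 to 0.888 within D14FL. Within D30FL, the most spread group, they ran from 0.711 to 0.865. Between groups the ranges overlapped these: 0.713 to 0.826 for Ori and D14FL, 0.616 to 0.853 for Ori and D30FL, and 0.769 to 0.866 for D14FL and D30FL. D30FL 3 correlated with Ori 1, Ori 2 and Ori 3 at 0.826, 0.848 and 0.853, and with D30FL 1 and D30FL 2 at 0.865 and 0.711. The 100 most abundant transcripts held between 28.0% and 36.1% of the FPKM in Ori and between 22.2% and 27.1% in later libraries. With that, the median log2 change of all 54200 tested transcripts was 0.38 at day 14 and 0.37 at day 30. Median-of-ratios scaling brought these medians to 0.04 and 0.06. Log2 changes are therefore given below after subtracting the median of all tested transcripts, with the standard error (SE) of the limma fit. The adjusted p and calls of single transcripts come from the test of the change before this subtraction against 0.

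**Figure D1:**
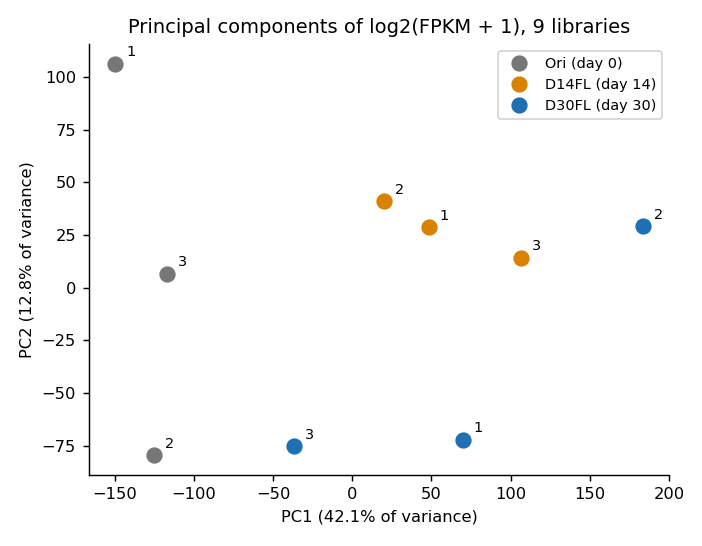
First (42.1% of variance) and second (12.8%) principal components of log2(FPKM + 1) in the 9 libraries, each point a library with its replicate number, coloured by group. The 3 Ori libraries have the lowest values on the first component, and D30FL 3, at -36.5, is the nearest later library.

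At day 14 the gut held more transcript of insulin, of several pancreatic digestive enzymes and of the stress-induced gene DDIT4 than at day 0, and less of TYMS, a gene of DNA synthesis. INS (TRINITY_DN22802_c0_g1_i1_1), which encodes insulin, rose from 0.443 ± 0.538 FPKM to 52 ± 23.6 (SD, n = 3 each), a log2 change of 4.79 (SE 0.37, adjusted p = 0.000591). DDIT4 (TRINITY_DN36882_c0_g1_i4_1), a stress-induced inhibitor of mTOR signalling, rose from 3.09 ± 0.329 to 215 ± 99.7 FPKM (SD, n = 3 each), a log2 change of 5.20 (SE 0.44, adjusted p = 0.000591). CEL, the bile salt-activated lipase of the pancreas (TRINITY_DN28199_c0_g1_i3_3), rose from 3.42 ± 3.74 to 419 ± 618 FPKM (SD, n = 3 each). TYMS, the enzyme that makes thymidylate for DNA synthesis, fell from 15.1 ± 6.4 to 2.17 ± 0.199 FPKM (SD, n = 3 each).

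**Figure D2:**
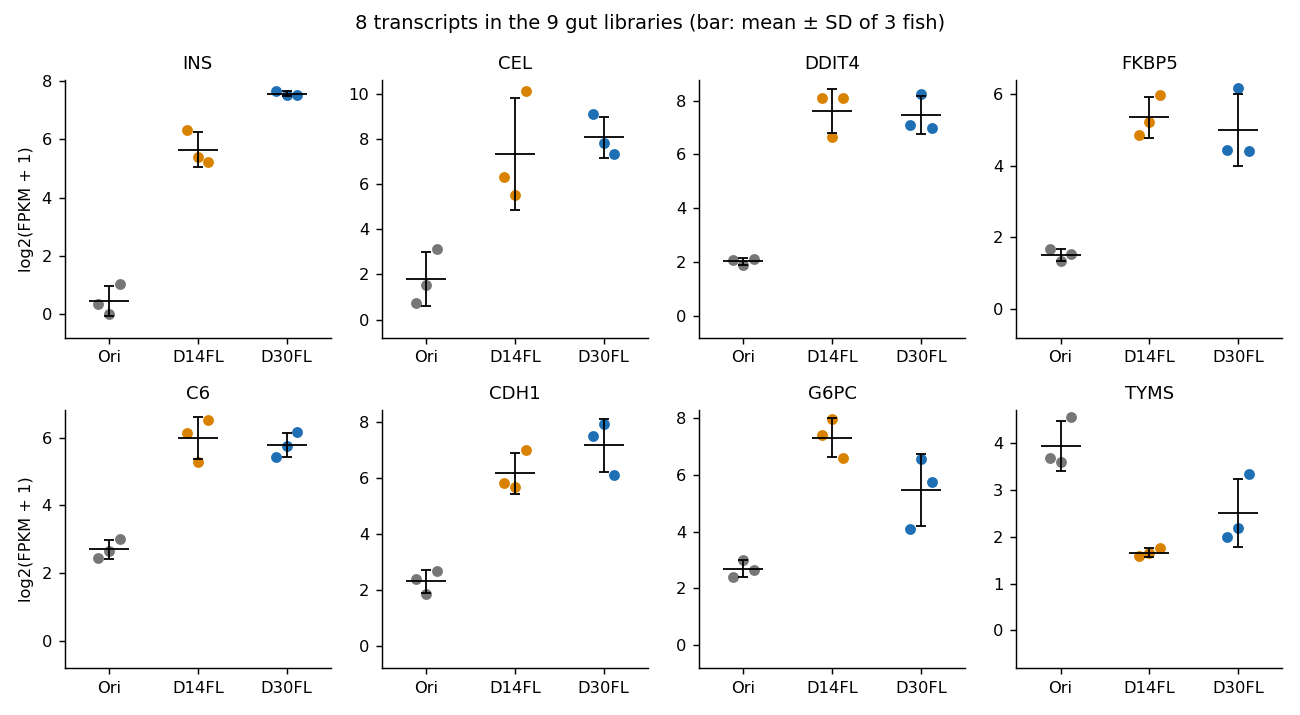
log2(FPKM + 1) of 8 transcripts in each library, points for fish and bars for the mean ± SD of 3 fish per group. INS lies between 0 and 1.03 in Ori, between 5.21 and 6.32 in D14FL and between 7.51 and 7.66 in D30FL, and TYMS is lower in the 6 later libraries than in Ori.

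Among pancreatic digestive enzymes, 3 of the 11 tested members rose, CEL and the lipase PNLIPRP2 among them, and 11 rose when adjusted over the list alone. The list median was 3.45 log2 units above that of all transcripts (camera adjusted p = 8.12e-06, and adjusted p = 0.751 with an estimated correlation). Transcripts named by the rule added TRY3, CELA2, CELA3 and TRY2, annotated as trypsins and elastases, with log2 changes between 4.66 and 5.28. Levels differed widely between the fish of D14FL, where CEL stood at 79.7, 44.4 and 1132 FPKM. PHKG, annotated as a phosphorylase kinase subunit, rose by 5.43 log2 units, and IGFBP-1, an insulin-like growth factor-binding protein, by 4.43. Under median-of-ratios scaling CELA2, CELA3 and IGFBP-1 were no longer called (adjusted p = 0.0504, 0.0622 and 0.0746).

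Of 26 glucocorticoid and acute stress genes, 6 rose, 9 adjusted over the list alone, and 0 fell in either count. FKBP5, a co-chaperone of the glucocorticoid receptor, rose by 3.46 log2 units (SE 0.47), KLF9, a transcription factor, by 3.32 (SE 0.58) and HSD11B2, which inactivates cortisol, by 2.18 (SE 0.36). The list median was 0.29 above that of all transcripts (camera adjusted p = 0.021, and adjusted p = 0.751 with an estimated correlation). The list was not called without D14FL 3 or with a filter on a mean FPKM of at least 5.

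Of 38 cell cycle genes, 3 fell and 0 rose, and adjusted over the list alone 15 fell and 1 rose. TYMS had a log2 change of -2.67 (SE 0.42), the mitotic kinase AURKA of -2.09 (SE 0.40) and RRM2, a subunit of ribonucleotide reductase, of -2.07 (SE 0.39). MKI67, a marker of dividing cells, had 3.85 FPKM in Ori and 0.715 in D14FL and did not pass (adjusted p = 0.0537, and 0.0318 under median-of-ratios scaling). The list median was -1.40 relative to all transcripts (camera adjusted p = 5.98e-19, and adjusted p = 0.751 with an estimated correlation). Genes of oxidative phosphorylation had a median of -1.03 relative to all transcripts (camera adjusted p = 2.27e-18, and adjusted p = 0.751 with an estimated correlation). Of its 74 members 1 rose, ATP5E, whose best protein match is a mammal and whose call ended under median-of-ratios scaling (adjusted p = 0.0898), and 0 fell; adjusted over the list alone 1 rose and 2 fell. A transcript of ND1, a mitochondrially encoded subunit of complex I (TRINITY_DN21591_c0_g1_i1_2), fell from 429 ± 360 to 12.4 ± 2.6 FPKM (SD, n = 3 each, adjusted p = 0.0156).

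Other lists whose medians lay above that of all transcripts were nutrient transporters (by 0.69), extracellular matrix and fibroblasts (0.57), circadian clock (0.55), endothelium (0.37) and autophagy and lysosome (0.28), with camera adjusted p of 0.032, 0.00585, 0.0366, 0.0489 and 0.0177. With an estimated correlation each of them had an adjusted p of 0.751 or 0.774. SLC1A1, a carrier of acidic amino acids, rose by 3.72 log2 units (SE 0.77) as 1 of 20 transporters, 6 adjusted over the list alone. THBS1 and MMP2, genes of matrix proteins, rose by 1.72 (SE 0.42) and 1.24 (SE 0.33) among 27 members, 7 adjusted over the list alone. ULK2 and MAP1LC3A, which act in autophagy, rose by 2.78 (SE 0.53) and 2.79 (SE 0.63) among 30, 4 adjusted over the list alone. NR1D2 and NFIL3, clock regulators, rose by 1.16 (SE 0.29) and 1.85 (SE 0.45) among 14, 6 adjusted over the list alone. PLVAP was the 1 riser among 16 endothelium genes, 3 adjusted over the list alone. The calls of autophagy and lysosome (adjusted p = 0.137) and of nutrient transporters, circadian clock and endothelium (adjusted p = 0.0693 for each) ended under median-of-ratios scaling, as did those of MAP1LC3A, MMP2, NR1D2, NFIL3 and PLVAP. A filter on a mean FPKM of at least 5 ended the calls of transporters, clock and endothelium, and quantile scaling those of clock and endothelium. List calls also ended without single libraries: matrix without D14FL 3; autophagy without Ori 2 or Ori 3; transporters without Ori 2 or D14FL 2; clock without Ori 2, Ori 3, D14FL 2 or D14FL 3; and endothelium without Ori 1, Ori 3, D14FL 1, D14FL 2, D14FL 3 or D30FL 2.

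Lower medians relative to all transcripts were found for sterol synthesis (-0.76, camera adjusted p = 0.000866), proteasome subunits (-0.50, 0.00922), ribosomal proteins (-0.43, 0.0287) and antioxidant defence (-0.41, 0.0258). With an estimated correlation their adjusted p were 0.751, 0.774, 0.784 and 0.751. No member of the sterol, proteasome or antioxidant lists passed over all transcripts, and adjusted over the list alone 4 antioxidant genes rose and 4 fell, with 0 in the sterol and proteasome lists. Ribosomal proteins were called lower although their median as fitted was -0.05 and their mean 0.11. Of 77 members 5 rose and 1 fell, 8 and 2 adjusted over the list alone, and the risers RPL27A, RPL39, RPL1 and RPL10 have mammals as their best protein match; their calls ended under median-of-ratios scaling. Sterol synthesis was not called without D14FL 2, proteasome subunits not without Ori 3, D14FL 1 or D14FL 2, and antioxidant defence not without Ori 1, Ori 3, D14FL 1 or D14FL 2 or under quantile scaling. Ribosomal proteins were not called without D14FL 3 or under quantile scaling, and without Ori 1 the test gave the other direction (median as fitted 0.0971).

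The skeletal muscle list was called lower (median -2.01 relative to all transcripts, camera adjusted p = 2.11e-07, and adjusted p = 0.232 with an estimated correlation), with 5 of 10 members lower. Transcripts behind it, such as those annotated MYLPF, CKM, TNNI2 and TNNT3, have chicken as their best protein match. CKM, TNNI2 and TNNT3 were listed at 0 in all 6 later libraries and had means of 9.6, 9.17 and 9.31 FPKM in Ori. Without transcripts matched to mammals, birds or bacteria the list was not called (adjusted p = 0.404). The lowest log2 change of all named transcripts, GAPDH (TRINITY_DN5420_c0_g1_i1_1; 38.7 ± 18.1 FPKM in Ori and 0.024 ± 0.0208 in D14FL, SD, n = 3 each), also has a bird as its best match.

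Altogether 1501 transcripts differed at day 14, 1176 higher and 325 lower (78.3% higher), of which 649 and 227 had no protein match. Scalings that bring the median change close to 0 gave another balance of calls, with 436 higher and 648 lower (40.2% higher) under median of ratios and 388 and 509 (43.3%) under quantile scaling; 761 of the 1501 calls remained under the former and 707 under the latter. Leaving out single libraries moved the count to 516 (Ori 1), 302 (Ori 2), 233 (Ori 3), 139 (D14FL 1), 261 (D14FL 2), 224 (D14FL 3), 772 (D30FL 1), 3649 (D30FL 2) and 2665 (D30FL 3). Of 62 named transcripts called at day 14, 13 stayed called under every alternative run, among them INS, DDIT4, FKBP5, HSD11B2, PNLIPRP2, C6, C7, CDH1 and G6PC.

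**Figure D3:**
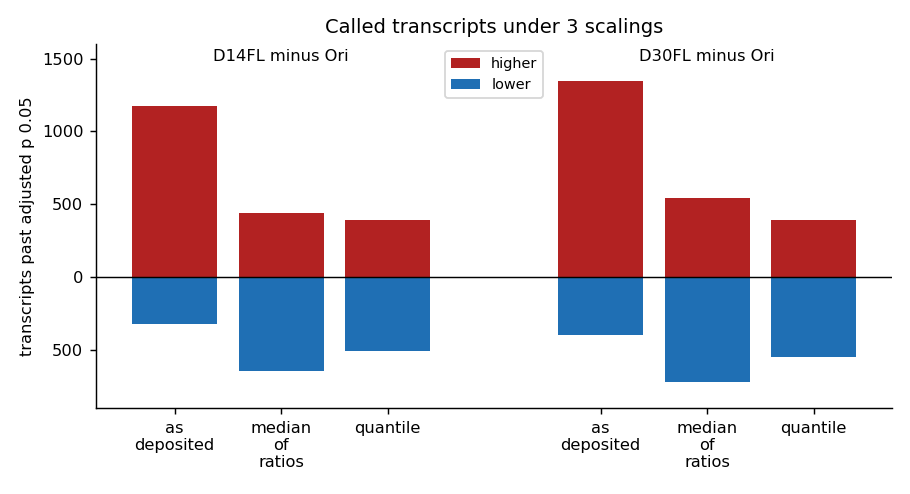
Numbers of transcripts called higher (upward bars) and lower (downward bars) at days 14 and 30 against Ori under 3 scalings of the FPKM. As deposited, 1176 and 1349 were higher, and under median-of-ratios scaling lower calls outnumbered higher ones (648 against 436 at day 14, 720 against 541 at day 30).

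At day 30 insulin, 8 of 11 pancreatic digestive enzymes and 6 of 26 glucocorticoid and acute stress genes were higher than at day 0. INS stood at 189 ± 10.8 FPKM (SD, n = 3), a log2 change of 6.73 against Ori (SE 0.37, adjusted p = 1.68e-05), and SST, which encodes the hormone somatostatin, rose by 3.31 (SE 0.79, adjusted p = 0.0358, and 0.0507 under median-of-ratios scaling). Of the 11 pancreatic digestive enzymes 8 rose and 11 did adjusted over the list alone, with a median 5.52 log2 units above all transcripts (camera adjusted p = 8.23e-09, and adjusted p = 0.711 with an estimated correlation). CEL stood at 309 ± 206 FPKM (SD, n = 3), a log2 change of 5.90 (SE 1.01), and the trypsin, elastase and chymotrypsin transcripts TRY1, TRY2, TRY3, ELA2A, CELA3 and CTRB rose by 6.58 to 7.68. HAAF, annotated as a hemagglutinin and amebocyte aggregation factor, and a transcript annotated as a vitelline membrane outer layer protein homolog rose by 7.10 (SE 1.31) and 7.03 (SE 1.46).

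Of 26 glucocorticoid and acute stress genes 6 rose, 10 adjusted over the list alone, led by DDIT4 (190 ± 101 FPKM, SD, n = 3; log2 change 5.05, SE 0.44), FKBP5 (3.12, SE 0.47), the transcription factor CEBPD (2.59, SE 0.48) and HSD11B2 (1.49, SE 0.36; adjusted p = 0.0558 under median-of-ratios scaling). The list median was 0.59 log2 units above all transcripts (camera adjusted p = 0.000449, and adjusted p = 0.711 with an estimated correlation). Heat shock proteins (0.56; camera adjusted p = 0.00291), extracellular matrix and fibroblasts (0.67; 0.00161), endothelium (0.51; 0.0185) and amino acid breakdown (0.90; 0.0299) were also called higher, with adjusted p of 0.711, 0.711, 0.786 and 0.82 with an estimated correlation. Their risers were HSF2 and DNAJB4 among 20 heat shock genes, THBS1, MMP2 and DCN among 27 matrix genes, ROBO4 and PLVAP among 16 endothelium genes, and ARG2 and TDO2, enzymes of arginine and tryptophan breakdown, among 19. Adjusted over each list alone, 6, 9, 4 and 4 members rose. Under median-of-ratios scaling DNAJB4, MMP2, DCN, ROBO4, PLVAP, ARG2 and TDO2 were not called. The heat shock list was not called without D30FL 1, matrix not without D30FL 3, endothelium not without Ori 1, Ori 3, D30FL 1 or D30FL 2, and amino acid breakdown not without Ori 2, Ori 3 or D30FL 2. A filter on a mean FPKM of at least 5 also ended the calls of endothelium and amino acid breakdown.

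Oxidative phosphorylation had a median of -0.81 relative to all transcripts, with 1 of 74 members lower (COX6B1, a subunit of cytochrome c oxidase; 98.2 ± 41.5 FPKM in Ori and 20.3 ± 17.1 in D30FL, SD, n = 3 each), which was also the 1 member adjusted over the list alone. The cell cycle list lay at -1.09, with 0 of 38 members called over all transcripts or adjusted over the list alone; under median-of-ratios scaling MKI67, PLK1 and TYMS passed (adjusted p = 0.0361, 0.0423 and 0.0482). In D30FL 3 both lists stood near Ori 1 and Ori 2 and below Ori 3. The median centred log2 value of oxidative phosphorylation was 0.269 in D30FL 3, -0.120 in D30FL 1 and -0.414 in D30FL 2, against 0.269, 0.285 and 0.546 in Ori 1, Ori 2 and Ori 3. That of cell cycle was 0.433 in D30FL 3, -0.284 in D30FL 1 and -0.569 in D30FL 2, against 0.434, 0.392 and 1.02 in the same Ori libraries. Camera gave adjusted p of 3.05e-13 and 5.61e-12 for these lists, and an adjusted p = 0.711 with an estimated correlation for each.

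Of the immune lists, antigen presentation, interferon response and T and natural killer cells were called lower at day 30, and complement, macrophages and granulocytes, B and plasma cells, antimicrobial effectors, microbe sensing and inflammatory cytokines were not called. Antigen presentation had a median of -0.91 relative to all transcripts (camera adjusted p = 7.79e-05, and adjusted p = 0.52 with an estimated correlation), with 1 of 19 members lower, PSMB9, an immunoproteasome subunit that fell by 2.75 on the log2 scale (SE 0.57), also the 1 adjusted over the list alone. Interferon response lay at -0.89 (camera adjusted p = 0.00019) and T and natural killer cells at -0.81 (0.0383), each with an adjusted p = 0.711 with an estimated correlation and 0 members called over all transcripts. Adjusted over the list alone, 1 interferon gene fell, IRF1 (44 FPKM in Ori, 16.4 in D30FL), and 0 T-cell genes. Interferon response was not called without Ori 3, and T and natural killer cells not under median-of-ratios scaling (adjusted p = 0.06), with the FPKM of all transcripts of a symbol summed, or without Ori 1, Ori 3, D30FL 1 or D30FL 2.

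Sterol synthesis (median -0.77 relative to all transcripts, camera adjusted p = 0.000382), brush border enzymes and microvillus proteins (-0.57, 0.00916), xenobiotic metabolism (-0.54, 0.0345) and antioxidant defence (-0.46, 0.0171) were called lower, each with an adjusted p = 0.711 with an estimated correlation. TM7SF2, a sterol reductase, was the 1 of 22 sterol genes to fall, by either adjustment, and SULT1C1, a sulfotransferase, the 1 of 21 xenobiotic genes, where adjusted over the list alone 2 fell and 1 rose. The detoxifying enzymes GSTM3 and CAT fell and SOD3, whose best match is a bird, rose among 35 antioxidant genes (SOD3 not under median-of-ratios scaling, adjusted p = 0.0619), where adjusted over the list alone 5 fell and 3 rose. No brush border gene passed by either adjustment. Brush border was not called without Ori 3 or D30FL 1, xenobiotic metabolism not without Ori 3, D30FL 1 or D30FL 3, and antioxidant defence not without Ori 1 or Ori 3. Quantile scaling also ended the calls of xenobiotic metabolism and antioxidant defence, and summing all transcripts of a symbol that of xenobiotic metabolism. The skeletal muscle list was called lower as at day 14 (median -1.73, camera adjusted p = 3.64e-07, and adjusted p = 0.261 with an estimated correlation), with 5 of 10 members lower by either adjustment and no call without transcripts matched to mammals, birds or bacteria (adjusted p = 0.668). A transcript annotated as N-acetylglucosamine-6-sulfatase, a lysosomal enzyme, fell from 53.1 ± 7.28 to 4.3 ± 2.1 FPKM (SD, n = 3 each), and 1 annotated as barrier-to-autointegration factor from 141 ± 76.9 to 11.5 ± 11.6.

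In all, 1746 transcripts differed at day 30, 1349 higher and 397 lower (77.3% higher), of which 797 and 279 had no protein match. Under median-of-ratios scaling 541 were higher and 720 lower (42.9% higher), and under quantile scaling 390 and 547 (41.6%), with 937 and 777 of the 1746 calls remaining. The count was 308 without Ori 1, 623 without Ori 2, 226 without Ori 3, 702 without D14FL 1, 1086 without D14FL 2, 98 without D30FL 1, 320 without D30FL 2 and 6466 without D30FL 3. Of 67 named transcripts called at day 30, 12 stayed called under every alternative run, among them INS, DDIT4, FKBP5, C6, C7, CDH1 and PCK1.

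**Figure D4:**
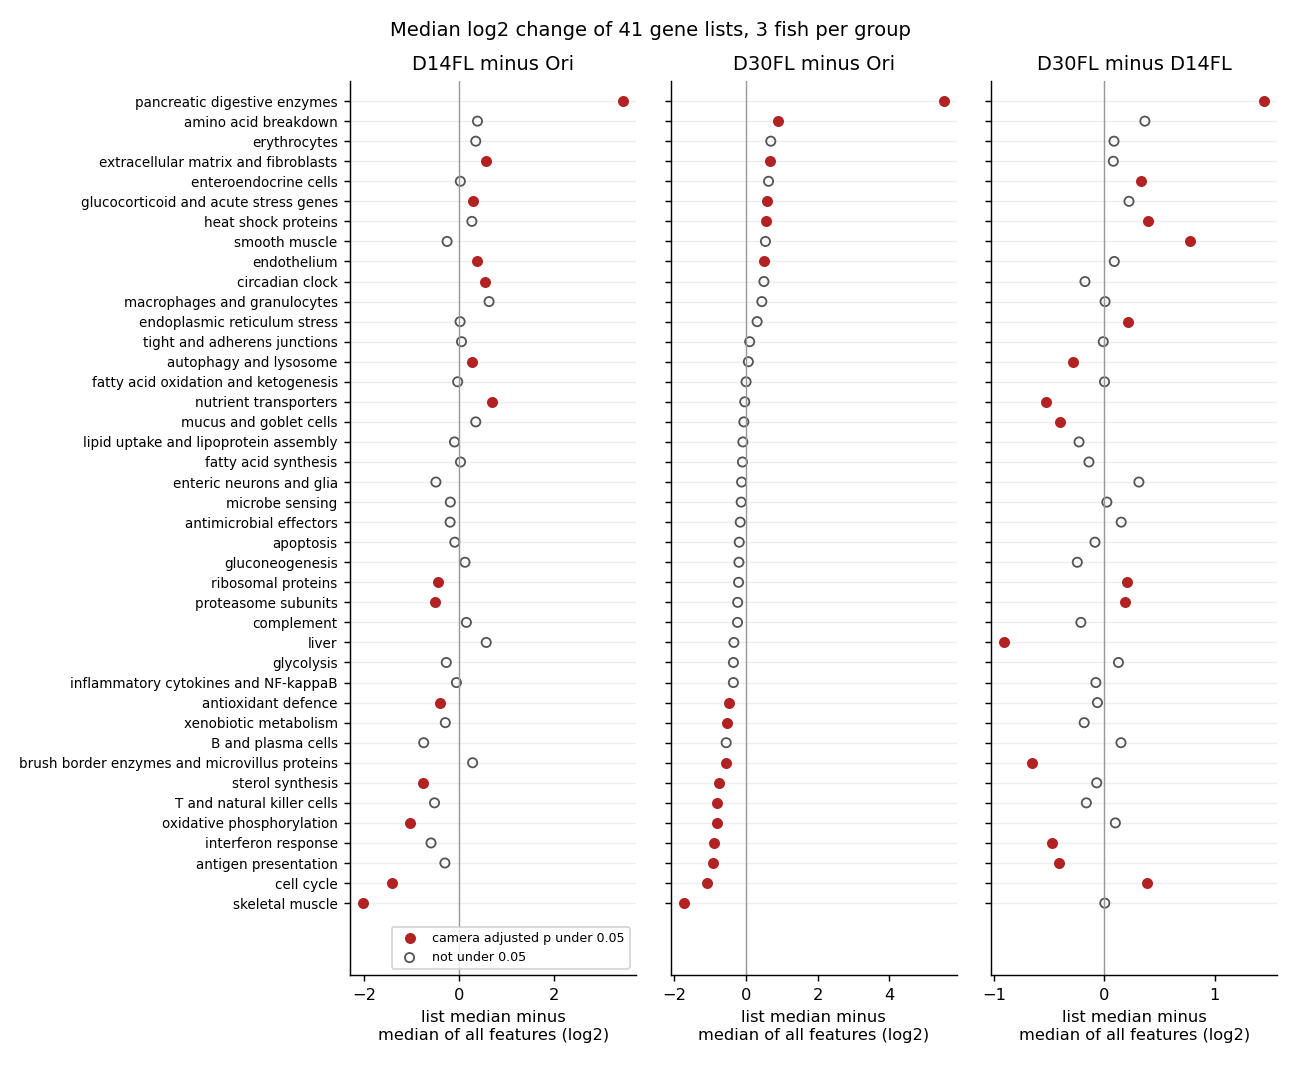
Median log2 change of each of 41 gene lists minus the median of all 54200 tested transcripts, for 3 contrasts of groups of 3 fish, with filled points for camera adjusted p under 0.05 at a preset correlation of 0.01. Pancreatic digestive enzymes lie at 3.45, 5.52 and 1.45, and cell cycle at -1.40, -1.09 and 0.38; no list was called with an estimated correlation.

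The changes at days 14 and 30 covaried more than in simulations of unchanged groups in which each transcript varied independently. The 2 contrasts shared 643 higher and 219 lower transcripts, and 1 changed in opposite directions. Across transcripts, the covariance of log2 changes was 0.589, against 0.149 in simulations of unchanged groups measured against the same Ori libraries, and the correlation 0.821 against 0.501. Transcripts of a real library vary together, while in the simulations such shifts average out over transcripts. The simulations therefore cannot show whether the covariance exceeds what the shared Ori libraries add. With 3 Ori libraries the controls could not be split to remove what the shared Ori libraries add to these calls.

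Between days 14 and 30, 1 transcript passed the test over all transcripts, and 0 of the named genes did. The called transcript (TRINITY_DN38823_c0_g2_i1_1), which has no protein match and is named here after its values were seen, fell from 28.8 ± 10.4 to 0.169 ± 0.194 FPKM (SD, n = 3 each; log2 change -4.62, SE 0.41, adjusted p = 0.006). An unadjusted p under 0.05 was found for 2079 transcripts, and no call was made without D14FL 1, D14FL 3, D30FL 2 or D30FL 3, while 2 were made without D14FL 2. Insulin had the smallest p of the named transcripts that were higher (52 FPKM at day 14 and 189 at day 30; log2 change 1.93, SE 0.37, adjusted p = 0.902). PENK, ACTA, DNAJC21 and a transcript of receptor expression-enhancing protein 5 were next. Lower, with small unadjusted p but not called, were amnionless, heme-binding protein 1 (58.9 and 20.8 FPKM, adjusted p = 0.989), the potassium channel annotated IK1 and the iron exporter SLC40A1 (61.3 and 14.1 FPKM).

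Between days 14 and 30 camera with its preset correlation called 15 lists, of which 0 were called with an estimated correlation or by fry, and 0 members passed over all transcripts. Brush border enzymes and microvillus proteins had a median of -0.65 relative to all transcripts (camera adjusted p = 7.6e-10, and adjusted p = 0.394 with an estimated correlation), and 7 of 20 fell adjusted over the list alone. The peptidases MEP1B (175 and 65.8 FPKM), ENPEP (156 and 52.6) and DPP4 (181 and 87) had the smallest p among them. Liver genes (-0.91), autophagy and lysosome (-0.29), antigen presentation (-0.41), nutrient transporters (-0.52), interferon response (-0.48) and mucus and goblet cells (-0.40) were also called lower. Their camera adjusted p were 6.88e-07, 0.000191, 0.000191, 0.000496, 0.00114 and 0.0198, and with an estimated correlation the adjusted p were 0.404, 0.854, 0.394, 0.394, 0.854 and 0.616. Of these 6 lists, 0 members passed over all transcripts or adjusted over the list alone. Members with an unadjusted p under 0.05 included the liver-made plasma proteins HPX (8.34 and 1.73 FPKM) and FGG (8.4 and 1.83), and the lysosomal proteins LAMP2 (542 and 249) and CTSZ (925 and 322). Antigen presentation was not called without D30FL 2, and mucus and goblet cells not without D14FL 1 or D30FL 2 or with a filter on a mean FPKM of at least 5.

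Called higher at day 30 than at day 14 were pancreatic digestive enzymes (1.45), smooth muscle (0.78), heat shock proteins (0.40), cell cycle (0.38), enteroendocrine cells (0.33), endoplasmic reticulum stress (0.21), ribosomal proteins (0.20) and proteasome subunits (0.19 log2 units above all transcripts). Camera gave adjusted p of 0.00114, 0.00204, 0.0198, 0.00204, 0.00204, 0.00189, 0.0198 and 0.0198, and with an estimated correlation the adjusted p were 0.854, 0.854, 0.854, 0.886, 0.633, 0.698, 0.886 and 0.886. Apart from insulin, in enteroendocrine cells, 0 members of these lists passed adjusted over the list alone. The chaperone HSPA5 had 50.6 ± 14.4 FPKM at day 14 and 189 ± 146 at day 30 (SD, n = 3 each), and TYMS had 2.17 ± 0.199 and 5.21 ± 3.38. Pancreatic digestive enzymes were not called without D14FL 1, D14FL 2 or D30FL 1, cell cycle not without D14FL 1, and without D30FL 3 the median of cell cycle as fitted was 0.0319 with the test in the other direction. Smooth muscle was not called without D14FL 2, heat shock and endoplasmic reticulum stress not without D14FL 1 or D30FL 1 (heat shock also not with a filter on a mean FPKM of at least 5), ribosomal proteins not without Ori 3, D14FL 3, D30FL 1 or D30FL 3, and proteasome subunits not without D14FL 1, D14FL 2, D30FL 1 or D30FL 3.

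The list counts were 14 of 41 at day 14, 16 at day 30 and 15 between them, and 0 in each contrast with an estimated correlation. Fry called 2, 1 and 0 lists in 1 direction and 33, 32 and 0 for change in either direction. Lists at day 14 numbered 9 without Ori 3 and 9 without D14FL 2, those at day 30 numbered 10 without Ori 3, and those between days 14 and 30 numbered 9 without D14FL 1.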

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

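The tests chosen only after the result was seen were those of scaling, of the chicken-matched transcripts, of library batches and of other splits for counts of transcripts, and the exception made for human and mouse matches below was also added after its result.

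Insulin and pancreatic enzymes were higher after release (median enzyme log2 change relative to all transcripts 3.45 at day 14 and 5.52 at day 30). Scaling of the libraries is argued against, since the enzyme median at day 30 was 5.61 under median-of-ratios scaling, while size factors of the 9 libraries differed by at most 0.838 log2 units. Pancreatic tissue taken with the gut of later fish may account for the pattern, and it predicts that insulin and the enzymes vary together between fish of a group. Over the 9 libraries, deviations from group means gave Pearson r = 0.0191 and Spearman rho = 0.05 for insulin (exact permutation p = 0.977 and 0.935 over 216 arrangements; r = 0.372 without the 2 farthest libraries), and r = 0.509 and rho = 0.583 for somatostatin (exact permutation p = 0.227 and 0.181, r = 0.292 without the 2 farthest; adjusted p of r over both relations 0.977 and 0.454). With 3 fish per group this leaves tissue sampling open, and it cannot be told apart from a response of the fish to the river, its food or the season, which was not tested.

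Of transcripts that best match chicken proteins, 17 of 25 tested were called lower at day 14, and of those that best match human or mouse proteins 52 of 173 were called higher, while the sum over chicken matches was 488 to 1024 FPKM in Ori, 3022 in D14FL 3, 1978 in D30FL 3 and 280 to 451 in the other 4 later libraries, so the direction of the sum rests on D14FL 3 and D30FL 3. Reads from another organism are a candidate explanation for the called chicken matches, which the values do not decide. The 17 had a mean under 0.1 FPKM in both later groups, but they were picked for being called lower. The same share among other lower calls was not computed, and a gene of the fish that falls to near 0 would look alike. Of the 25 tested 68% were called, against 2.65% of transcripts matched to none of chicken, human and mouse. A Fisher exact test against all other tested transcripts gave p = 2.66e-21. It counts the calls that raised the question and takes transcripts of the same libraries as independent, so it adds no support. The 11 with a listed identity had a median of 99.5%, against 73.96% for 3766 transcripts matched to sterlet. All identities given here belong to the KEGG match, which can differ from the best match that gives the species. They are thus not identities to chicken, sterlet, human or mouse proteins as such. Of the called human and mouse matches, 19 had a mean under 0.1 FPKM in Ori, fewer than the bound set beforehand as arguing against foreign reads (under 5 in 10). By that bound the result argued against foreign reads. An exception was made after the result was seen, because the bound presumes sequences near 0 in Ori. All human matches, called or not, summed to a mean of 1132 FPKM in Ori. The 66 uncalled human and mouse matches with an identity had a median of 100% and the called ones 98.01%. Since these identities are of the KEGG match, they do not decide the question, and foreign reads are neither shown nor excluded there. Library batches, which no label gives, cannot be told apart from the groups, although 0 of these transcripts were called between days 14 and 30 by limma (where 2079 transcripts of all kinds had an unadjusted p under 0.05 and 1 was called).

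More transcripts were called higher than lower after release (78.3% higher at day 14 and 77.3% at day 30). Under median-of-ratios scaling the shares were 40.2% and 42.9%, but that scaling centres the changes (medians 0.04 and 0.06), which sets the balance, so it does not decide whether the scaling of the deposited values is the cause, and this stays open. A larger share of the Ori values taken by a few transcripts may contribute: the 1000 most abundant held 57.4% of the FPKM in Ori and 50.8% in each later group. Dividing by the sum outside them brought the median log2 change at day 14 from 0.384 to 0.200, short of the bound set beforehand (below 0.5 of the value as deposited), and at day 30 from 0.372 to 0.171, which is past it, so its part stays open. No biological explanation of the balance was tested.

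TRINITY_DN38823_c0_g2_i1_1 differed between days 30 and 14, by -4.62 log2 units in the limma contrast already given above (adjusted p = 0.006). Its call ended without D14FL 1, D14FL 3, D30FL 2 or D30FL 3. A pseudocount of 0.01 and a fit on only the 2 groups compared also ended it. No fish kept from release were sampled, so this difference cannot be ascribed to release. Transcripts matched to mouse proteins alone, of which 17 of 34 tested were called at day 14 and 4 of 34 at day 30 (Fisher exact p = 4.54e-18 and 0.0231), summed to 198 ± 56.8 FPKM in D14FL and 113 ± 31.3 in D30FL, above the 24 ± 3.68 of Ori (SD, n = 3 each). The Fisher test takes transcripts of the same libraries as independent, so its p does not measure the spread between fish. Transcripts matched to bacteria summed to 401 FPKM in Ori 1 and 269 in Ori 2 and were listed at 0 in Ori 3 and the 6 later libraries. Single libraries were not tested as outliers within groups of 3.

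Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Every other split mixes the groups, so any difference between them, whatever its cause, enters the residual spread and lowers the count of transcripts. Low counts in the other splits are therefore no support for the real count. For transcripts, 1 of 10 splits gave a count as large at day 14 (1501, highest other split 1), 1 of 10 at day 30 (1746, highest other 2) and 5 of 10 between days 14 and 30 (1, highest other 8). For lists the numbers were 4 of 10 at day 14 (14, highest other 19), 2 of 10 at day 30 (16, highest other 17) and 2 of 10 between days 14 and 30 (15, highest other 15), so list counts as large also came from splits that mix the groups.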

How the results depend on the processing

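The alternative chosen only after the result was seen was the fit without transcripts matched to mammals, birds or bacteria, with 1148 transcripts called at day 14, 1492 at day 30 and 1 between them. Counts of transcripts at days 14 and 30 were 897 and 937 under quantile scaling, 4334 and 5184 at an adjusted p under 0.1, 3335 and 507 in fits on only the 2 groups compared, and 315 and 357 with the replicate number as a block. The 9 pairs of libraries of the same number had residual correlations from -0.315 to 0.084, with 0 above 0.1, against 3 of 18 other pairs. Library weights gave 6730, 18672 and, between days 14 and 30, 6462; the weights came with a convergence warning, so these counts are not reliable. Between days 14 and 30 the count was 0 with a pseudocount of 0.01 and 0 on only the 2 groups compared. With an estimated correlation 0, 0 and 0 lists were called. The covariance of day 14 and day 30 changes was 1.587 with a pseudocount of 0.1, a setting at which no simulation of unchanged groups was run. The looser threshold raises counts by construction; for the other settings the cause was not tested. The block also ended the call of endothelium at day 14.

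Without single libraries, counts ran from 139 (D14FL 1) to 3649 (D30FL 2) at day 14, from 98 (D30FL 1) to 6466 (D30FL 3) at day 30 and from 0 to 2 between them, lists from 9 to 17, from 10 to 18 and from 9 to 19, and the covariance from 0.470 (D30FL 2) to 0.703 (D30FL 3). The direction of the list test reversed for ribosomal proteins at day 14 without Ori 1 (median as fitted 0.0971, -0.233 without Ori 2), and between days 14 and 30 without D30FL 3 for cell cycle (0.0319, 0.527 without D30FL 2) and oxidative phosphorylation (-0.134, 0.278 without D30FL 2). Medians of further lists changed sign without a call in the other direction. Among them at day 14 were smooth muscle (-0.894 without Ori 1 to 0.946 without Ori 2) and interferon response (-0.627 under median-of-ratios scaling to 0.483 without Ori 3). Neither was called there in the main fit, but each was called in some fits with a library left out. The cause was not tested. Of the named transcripts called, 13 of 62 at day 14 and 12 of 67 at day 30 stayed called under every alternative run. Over all named transcripts, most of them not called, calls were lost in 380 of 3962 results at day 14, 416 of 4067 at day 30 and 0 of 3912 between them, gained in 211, 245 and 88, and reversed in 0. Of the gains, 59, 92 and 88 came from the library weights, whose counts are not reliable. The looser adjusted p under 0.1 gave 44, 55 and 0 of them. A call can be lost only where 1 was made. The 380 and 416 losses thus fall on the 62 and 67 called transcripts alone, each with 21 to 23 alternatives. Between days 14 and 30 no named transcript was called, so no loss was possible. List calls were lost in 53, 45 and 37 of 440 results each, gained in 13, 7 and 11, and reversed in 1, 0 and 2. Those results cover the 26 lists called in any contrast, of which 14, 16 and 15 were called in these contrasts. Depth is unknown, so what it limits was not computed.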

Other observations

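The tests in this part were planned, except that the grouping of genes across lists in these paragraphs was chosen after the result was seen.

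C6, C7, CDH1, G6PC and PCK1 were higher at days 14 and 30 than at day 0. C6 and C7, which encode components of the membrane attack complex, rose from 5.57 ± 1.27 to 66.2 ± 26.2 FPKM and from 11.9 ± 2.48 to 96.3 ± 28.2 at day 14 (SD, n = 3 each), with log2 changes relative to all transcripts of 2.90 and 2.50. They stood at 55.3 ± 14.4 and 105 ± 16.7 at day 30 (SD, n = 3 each), where CD59, an inhibitor of that complex, also rose (0.96, adjusted p = 0.0401, and 0.149 under median-of-ratios scaling). CDH1, the adhesion protein of epithelial cells, rose from 4.06 ± 1.43 to 78.2 ± 43.7 and 164 ± 88.9 FPKM (SD, n = 3 each), and the tight junction gene CLDN4 rose at day 30 by 2.97 (adjusted p = 0.0365, and 0.0505 under median-of-ratios scaling). G6PC, which releases free glucose, rose from 5.57 ± 1.35 to 171 ± 77.1 FPKM at day 14 and stood at 54.1 ± 38.9 at day 30, and PCK1, an early enzyme of gluconeogenesis, rose from 0.69 ± 0.469 to 7.7 ± 1.76 and 32.7 ± 31.7 (SD, n = 3 each). Median-of-ratios scaling ended the calls of PCK1 at day 14 (adjusted p = 0.0657) and G6PC at day 30 (0.0512).

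Among genes of lipid handling, ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.39 at day 14 and 2.52 at day 30, the lipid droplet protein PLIN2 by 2.30 and 2.91 and the cholesterol exporter ABCA1 by 2.70 and 2.58 log2 units relative to all transcripts. PLIN2 at day 14 was not called under median-of-ratios scaling (adjusted p = 0.0694). CDKN1A, an inhibitor of the cell cycle, rose by 2.82 and 3.06. FADS2, a fatty acid desaturase, had 12.1 ± 0.924 FPKM in Ori and fell to 2.83 ± 1.75 at day 30 (SD, n = 3 each).

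The lists these genes belong to were not called by camera as wholes. Camera adjusted p at day 14, at day 30 and between them were 0.0685, 0.775 and 0.0795 for complement, 0.117, 0.202 and 0.856 for tight and adherens junctions, 0.588, 0.854 and 0.453 for gluconeogenesis, 0.588, 0.854 and 0.323 for lipid uptake and lipoprotein assembly, 0.831, 0.671 and 0.604 for fatty acid oxidation and ketogenesis, 0.984, 0.791 and 0.296 for fatty acid synthesis, and 0.996, 0.791 and 0.453 for apoptosis. The other lists called in no contrast were glycolysis (0.117, 0.258, 0.606), B and plasma cells (0.0685, 0.246, 0.453), enteric neurons and glia (0.195, 0.854, 0.092), antimicrobial effectors (0.492, 0.791, 0.579), erythrocytes (0.588, 0.464, 0.584), microbe sensing (0.588, 0.636, 0.737), macrophages and granulocytes (0.688, 0.791, 0.941) and inflammatory cytokines and NF-kappaB (0.973, 0.791, 0.606).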
